A study of Mus musculus with 2 samples.

How the data were processed

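Upper back skin of SKH-1 mice injected intradermally with C. acnes or with clostridial culture medium was profiled by 10x Genomics 3' single-cell RNA-seq on day 3. Per the labels, 3 punch biopsies of 6 mm were pooled per condition, dead cells were removed and red cells lysed. The submitters' processing notes name Cell Ranger 3.0.1, Seurat 3 and mm10. The order and settings of their steps, and their handling of doublets, are not given in the sources used here. The deposited table holds the count of UMIs per gene and cell as whole numbers, and the authors' metadata give the total count per cell, the library, the cluster and the cell class. The deposited mitochondrial column holds a fraction of each cell's UMIs, although its name reads as a percent. Column sums of the table equalled the deposited totals in all 28258 cells. A second deposited table gives the authors' clustering of 7750 of the 9342 cells classed Fibroblast. How these were chosen is not given in the sources used here.

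The cells were used as deposited, with no further filter and no doublet caller. The lowest total was 500 UMIs and the lowest number of genes 101 in the control library and 112 in the infected library, and the highest mitochondrial share of a cell lay just under 10.0%. Depth was 93347941 UMIs in the control library and 134235035 in the infected library. The table lists 22514 genes, of which 22225 had a UMI. Positions were taken from GENCODE M21 on GRCm38 (mm10), in which 22171 of the symbols (98.5%) were found. The annotation release used by the authors is not given in the sources used here.

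UMIs were summed per library and population and scaled to counts per 1000000 (CPM) of that population's UMIs. The log2 ratio of infected over control used a pseudocount of 10 CPM. Levels carry exact Poisson 95% intervals and shares exact Clopper-Pearson 95% intervals, which cover counting error only. The limit given for 0 of the thinned cells is that of 3 counts. With 1 library per group no test was made. Populations were the 7750 fibroblasts and the authors' other classes. A class was compared by name only if none of its clusters had more markers of another class than of its own among its 10 leading genes. The Fibroblast and Lymphoid classes failed this, and the lymphoid population was taken without cluster 20. The fibroblast population was the authors' second clustering as deposited, with the cells of cluster 5 of all cells that it keeps. Shares of cells with a Camp UMI were computed after each cell was thinned to 1000 UMIs without replacement, leaving out shallower cells.

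The gene lists, the marker lists, the comparisons and the naming rule were fixed before the data were examined. Tests of explanations were set afterwards, and the closing part says which followed the results they measure. Named genes in fibroblasts are the 12 highest and 12 lowest log2 ratios among genes with at least 100 UMIs over both libraries, without mitochondrial, ribosomal protein, haemoglobin and unnamed genes. In each other population they are the 5 highest and 5 lowest. From each list they are up to 2 members at either end, and Camp. Not every gene that the rule names is reported here. Saa3, the sex-linked and haemoglobin genes, Gm42418, Plac8, Ngp and Il1b were named after their values were seen, as were leading genes of clusters. Each of 20 lists was described by its median log2 ratio and its percentile among 10000 random lists of the same size matched on mean expression in 20 bins. Reads of the Gbp family, of Saa1 and Saa2 and of the Serpina3 family may be shared among similar copies, so their single values are uncertain.

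Alternatives were TMM scaling, pseudocounts of 1 and 50 CPM, minimums of 20 UMIs and of none, equal weight for every cell, removal of the 5% of cells with the most and the 5% with the fewest UMIs, removal of fibroblasts with a UMI of Krt14, Krt5, Krt10, Ptprc, S100a8 or S100a9, weighting of both libraries to the same makeup of the clusters with at least 30 cells in each library, shares among non-immune cells, no thinning, and thinning to 500 UMIs. Alternatives chosen after seeing the data were the whole Fibroblast class, the fibroblasts outside clusters 5, 17 and 23 of all cells, Camp without the 5 richest cells per library, the antimicrobial list without S100a8 and S100a9 with and without the removal of cells with marker UMIs, and the assignment of fibroblasts to control clusters. That assignment used a multinomial model of genes differing less than 1.5-fold between the libraries when both were weighted to the same makeup of clusters. The log2 ratio and its interval were tested on simulated data in which 50 genes at each true fold were changed among 11175. The median error was -0.0021 at a fold of 0.25, -0.016 at 0.5, 0.0016 at 2 and 0.014 at 4, and the intervals held the true value for 94%, 96%, 96% and 94% of genes. The simulated counts were Poisson draws around the control profile, without variation between cells or animals. This coverage therefore checks the calculation and not how well the intervals describe the data. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, matplotlib 3.10.9, R 4.3.3 and edgeR 4.0.16 were used.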

Results

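Single-cell RNA-seq was performed on upper back skin of SKH-1 mice, a hairless laboratory strain, after intradermal injection of Cutibacterium acnes, a skin bacterium associated with acne, or of its culture medium. There was 1 library per group. Each library was made from 3 pooled punch biopsies of 6 mm taken on day 3. The media control library held 12205 cells and 93347941 unique molecular identifiers (UMIs), with a median of 5424 UMIs per cell. The C. acnes infected library held 16053 cells and 134235035 UMIs, with a median of 6536 per cell. No difference between the libraries has a replicate check, so no test was made. Intervals are exact 95% intervals that cover counting error only.

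The libraries also differed in sex-linked transcripts, which the labels do not mention. Xist, the transcript that silences an X chromosome in female cells (chromosome X, 103460366 to 103483254, GRCm38), had 87321 UMIs in the control library and 12 in the infected library. The Y-linked genes Ddx3y, Eif2s3y, Uty and Kdm5d had 2 UMIs together in the control library and 23169 in the infected library. A UMI of these Y-linked genes was seen in 64.7% of infected cells (64.0 to 65.5%) and in 0.0164% of control cells (0.00198 to 0.0592%). Infection and the animals' sex were therefore not separable at any gene reported here.

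To describe the cellular makeup of the injected skin, the share of each cell class named by the authors was compared between the libraries. Keratinocytes, the epithelial cells of the epidermis and hair follicle, made up 34.9% of control cells (34.1 to 35.8%) and 25.6% of infected cells (24.9 to 26.3%). Myeloid cells made up 21.6% (20.9 to 22.3%) and 14.6% (14.1 to 15.2%), endothelial cells 2.72% (2.44 to 3.02%) and 1.59% (1.40 to 1.79%), and melanocytes 1.64% (1.42 to 1.88%) and 0.573% (0.462 to 0.702%). The authors' Fibroblast class held 26.2% of control cells and 38.3% of infected cells, and the Lymphoid class 12.9% and 19.3%. These 2 classes contained clusters led by genes of other cell types, so they were compared by cluster number.

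**Figure D1:**
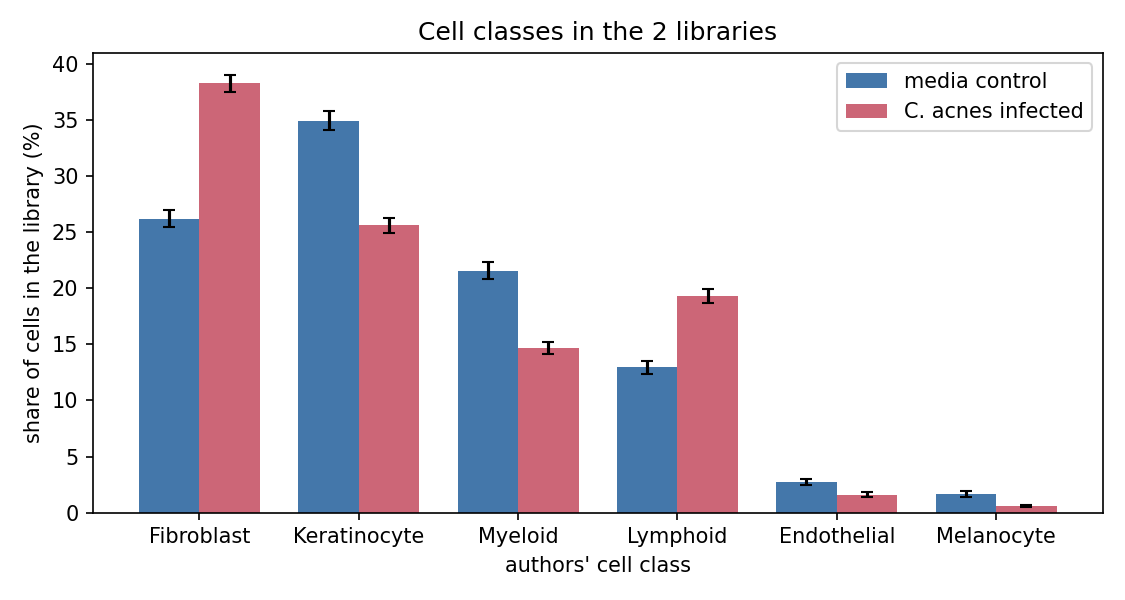
Share of cells (%) in each of the 6 cell classes named by the authors, for the media control library and the C. acnes infected library. Bars are shares and error bars are exact 95% binomial intervals; the Fibroblast bars reach 26.2% and 38.3%, and the Keratinocyte bars 34.9% and 25.6%.

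In the clustering of all cells, among clusters whose 10 leading genes all differed by less than 2-fold between control and infected cells of that cluster, the macrophage cluster 3, led by Mmp12 and Lyz2, held 13.9% of control cells and 4.85% of infected cells. The neutrophil cluster 12, led by Retnlg and Ngp, held 2.72% and 2.41%. The T cell cluster 7, led by Cd7, Cd3g and Cd3e, held 5.51% and 6.67%. The differentiated keratinocyte cluster 6, led by Sprr2b and Krt6b, held 4.33% and 7.60%. Fibroblast cluster 1, led by Cyp26b1 and Cpxm1, held 7.70% and 14.6%. A further monocyte and macrophage cluster, 11, with Chil3, Ly6c2, C1qa and C1qb among its leading genes, held 1.79% of control and 4.83% of infected cells. It lies outside this rule, since 5 of its 10 leading genes differed at least 2-fold. Macrophages as a whole are therefore not described by cluster 3 alone. The 4 clusters with more markers of another cell type than of their own class among their 10 leading genes were 5, 17 and 23 of the Fibroblast class and 20 of the Lymphoid class. Cluster 17, led by the myeloid genes Acod1 and Il1b, held 0.639% of control cells and 1.57% of infected cells. Cluster 23, led by the pericyte genes Rgs5 and Tagln, held 0.426% and 0.492%, and cluster 20, led by haemoglobin and mast cell genes, held 0.860% and 0.772%. Cluster 5, led by Spp1 and Cfd with the muscle gene Acta1 and the adipocyte gene Car3, held 9.38% and 4.63%. Cluster 5 failed on Acta1 and Car3 alone. Its leading genes Spp1, Col5a3, Lrrc15 and Tnn also lead cluster 3 of the authors' fibroblast clustering, so it is not shown to be another cell type.

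Gene levels were then compared in fibroblasts, since the study's title names dermal preadipocytes. The 7750 cells of the authors' fibroblast clustering were used, 2668 control cells and 5082 infected cells. That clustering left out 531 of 3199 control cells of the class (16.6%) and 1061 of 6143 infected cells (17.3%). It kept cells of cluster 5 of all cells, which were 844 of the control fibroblasts (31.6%) and 476 of the infected fibroblasts (9.37%), and 1 control cell of cluster 23. Each of its own 10 clusters passed the marker check. Most of them had no listed marker of any class among their leading genes, and cluster 4 had 1 fibroblast and 1 myeloid marker. The check therefore could not establish what these clusters are. A comparison outside clusters 5, 17 and 23 of all cells was added after the data were seen. That comparison may leave out fibroblasts as well as other cell types, since cluster 5 shares leading genes with fibroblast cluster 3. Interferon-inducible genes made up most of the genes with the highest ratios in the infected library. Cxcl9, a chemokine that attracts T cells (chromosome 5, 92321347 to 92328079), stood at 17.7 CPM, counts per 1000000 fibroblast UMIs (15.8 to 19.9), in control fibroblasts and 827 CPM (818 to 836) in infected fibroblasts, a log2 ratio of 4.91. Cxcl10, a ligand of the same receptor, stood at 32.3 and 803 CPM. Iigp1, an immunity-related GTPase that acts on vacuoles holding pathogens (chromosome 18, 60376027 to 60392634), stood at 52.6 CPM (49.2 to 56.2) and 1186 CPM (1175 to 1197). Lcn2, which sequesters bacterial siderophores (chromosome 2, 32384633 to 32388252), stood at 278 CPM (270 to 286) and 1936 CPM (1922 to 1950).

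The 12 highest log2 ratios in fibroblasts were those of Cxcl9, Cxcl10, Iigp1, Igtp, Ddx3y, Gbp4, Gbp2, Saa2, Ifi47, Lcn2, Serpina3f and Irgm1. Igtp, Ifi47 and Irgm1 are further immunity-related GTPases, with log2 ratios of 3.63, 2.80 and 2.64. The guanylate-binding proteins Gbp4 and Gbp2, which target membranes around intracellular microbes, had log2 ratios of 3.19 and 3.19. The acute phase gene Saa2 had a log2 ratio of 3.00 and the serine protease inhibitor gene Serpina3f one of 2.69. The Gbp, Saa and Serpina3 families hold closely similar copies, so the split of UMIs among their members is uncertain. The Y-linked Ddx3y had 1 UMI in control fibroblasts and 3504 in infected fibroblasts. With both libraries weighted to the same makeup of fibroblast clusters, which leaves out clusters 2, 5 and 6, the log2 ratio of Lcn2 was 0.63 in place of 2.76 and that of Saa2 was 1.16, while that of Cxcl9 was 5.13 and that of Iigp1 was 3.95. In fibroblasts without a keratin or immune marker UMI, Lcn2 was at 1.35, Saa2 at 2.25, Cxcl9 at 3.90 and Cxcl10 at 4.94.

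The 12 lowest log2 ratios were those of Xist, Igfbp2, Thbs4, Fibin, Tnn, Mmp19, Lrrc15, Spp1, Ptn, Ncam1, Ednrb and Col5a3. Igfbp2, which binds insulin-like growth factors, was at 198 CPM (191 to 205) in control and 46.2 CPM (44.0 to 48.4) in infected fibroblasts, a log2 ratio of -1.89. Thbs4 and Tnn encode matrix glycoproteins, and their log2 ratios were -1.68 and -1.62. The protease gene Mmp19 had a log2 ratio of -1.57 and the secreted phosphoprotein gene Spp1 one of -1.50. Col5a3, a chain of type V collagen, stood at 781 and 286 CPM. Fibin, Lrrc15, Ptn, Ncam1 and Ednrb had log2 ratios of -1.63, -1.56, -1.48, -1.44 and -1.42. With both libraries weighted to the same makeup of fibroblast clusters, the median of these 12 ratios moved from -1.56 to -0.65 and that of Spp1 from -1.50 to 0.18. Outside clusters 5, 17 and 23 of all cells the median of the 12 was -1.26, with Spp1 at -0.39, Tnn at -0.056, Ednrb at -0.026, Lrrc15 at -0.79 and Col5a3 at -0.85. In the 278 control and 252 infected fibroblasts without a keratin or immune marker UMI, Spp1, Thbs4 and Ednrb were further from 0, at -2.58, -2.69 and -2.42, and Igfbp2 was nearer, at -1.11. Spp1, Col5a3, Tnn and Lrrc15 are leading genes of fibroblast cluster 3, which held a smaller share of the infected fibroblasts.

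**Figure D2:**
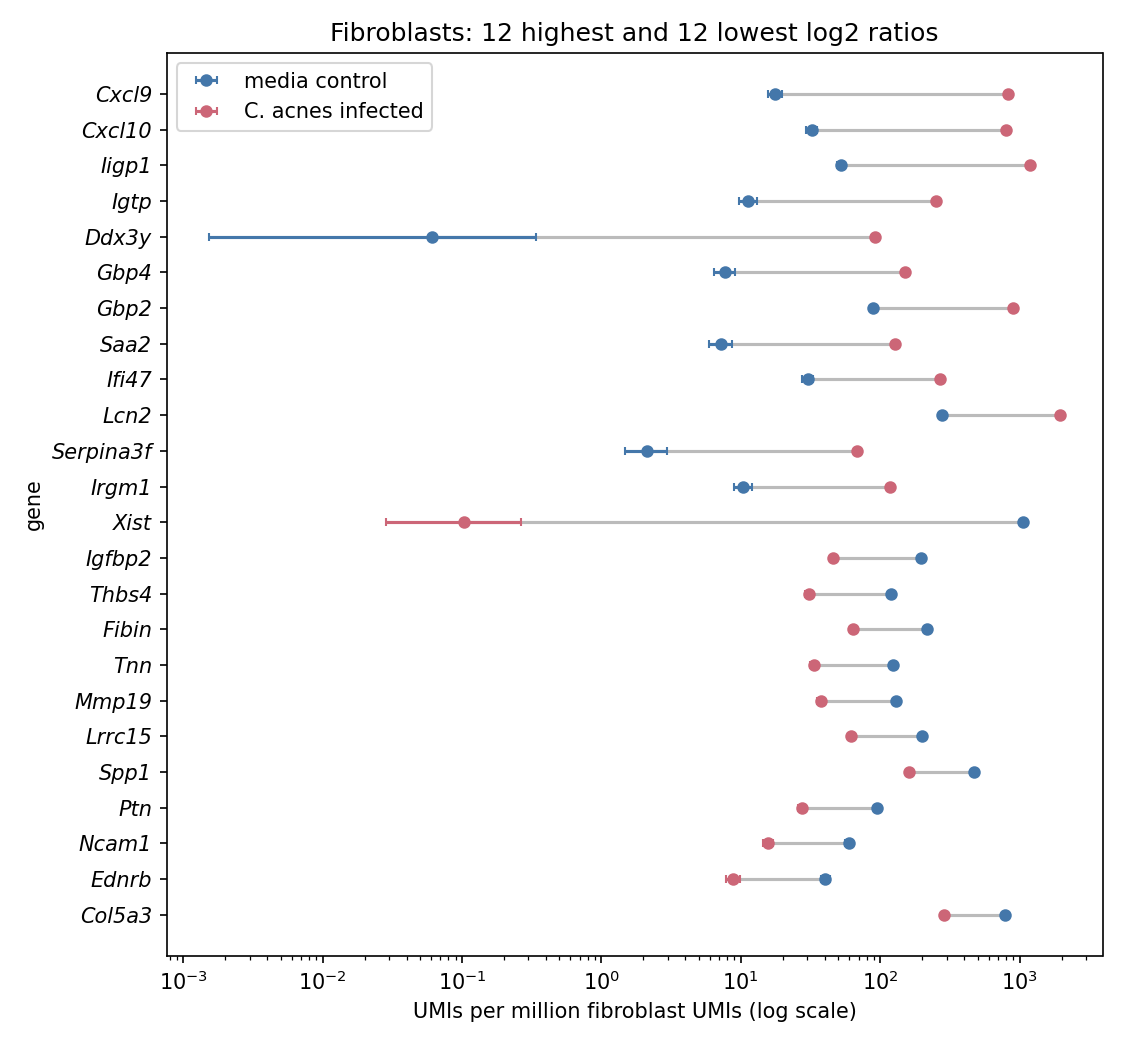
Levels of the 24 named genes in fibroblasts of the media control library and of the C. acnes infected library, in CPM on a log scale. Points are levels, error bars are exact 95% Poisson intervals, and grey lines join the 2 libraries; Cxcl9 goes from 17.7 in control to 827 in infected fibroblasts.

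Transcripts listed as markers of other cell types and markers of RNA quality also differed between the fibroblasts of the libraries. The haemoglobin transcript Hbb-bs was at 638 CPM in control and 74.6 CPM in infected fibroblasts. Gm42418, which overlaps ribosomal RNA, was at 3178 and 626 CPM. Summed macrophage and monocyte markers were at 256 and 931 CPM, of which Plac8 accounted for 199 and 862 CPM, while Lyz2 stood at 29.5 and 23.2 CPM. Summed neutrophil markers were at 199 and 307 CPM, and T and NK cell markers at 13.4 and 43.6 CPM. Dendritic cell markers, among them H2-Ab1, H2-Aa and Cd74, were at 96.7 and 237 CPM, and skeletal muscle markers at 33.6 and 10.9 CPM. Whether the UMIs of the dendritic cell list came from dendritic cells or from the fibroblasts was not tested. Summed pericyte and smooth muscle markers were at 315 and 136 CPM.

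Gene lists were used to ask which programmes differed in infected fibroblasts. The interferon response list stood highest, with a median log2 ratio of 1.39 over 26 measured members. Of these, 16 were at least 2-fold higher, led by Iigp1 at 4.26 and Igtp at 3.63, and none was 2-fold lower. Isg15, Ifit1 and Irf7 were among these 16. The lowest members, the antiviral genes Mx1 and Rsad2, had log2 ratios of 0.06 and -0.38, and with the same makeup of clusters Rsad2 was at 0.40. Mx1 stood at 2.00 and 2.53 CPM, under the pseudocount of 10 CPM, which draws its ratio toward 0. The acute phase and complement list had a median of 0.77, with 7 of 16 members at least 2-fold higher, led by Saa2 at 3.00 and Saa1 at 2.42, and the lowest members Cp and Serpina3g at 0.34 and 0.32. The antimicrobial protein list had a median of 0.51, with 3 of 11 members at least 2-fold higher. These were Lcn2, S100a8 and Saa3, while Reg3g, an antibacterial lectin gene, had a log2 ratio of -0.67. S100a8, a neutrophil and keratinocyte transcript, stood at 59.6 and 143 CPM in fibroblasts and at 115 and 263 CPM in lymphoid cells. Each of the 3 medians lay above all of 10000 random lists matched on expression, as a description of these libraries. With the same makeup of clusters the interferon median was 1.28, the acute phase median 0.17 and the antimicrobial median 0.05, with Saa1 at 0.66 and Cp at -0.24. That weighting leaves out clusters 2, 5 and 6. In infected cells of clusters 2 and 5 the summed acute phase list stood at 45145 and 49400 CPM. The summed antimicrobial list stood there at 31438.5 and 37392.7 CPM. Those were the highest sums among clusters with at least 30 cells in a library. The lower acute phase and antimicrobial medians therefore do not separate makeup from response. The removal of fibroblasts with a keratin or immune marker UMI sets S100a8 and S100a9 to 0, so the antimicrobial list was repeated without these 2 genes, a choice made after the data were seen. Its median over 9 members was then 0.22 in all fibroblasts and 0.0037 in those without a marker UMI. Reg3g was at -1.42 in the latter cells, on 19 control and 0 infected UMIs. Their median depths were 4113.5 UMIs in control and 1460.5 UMIs in infected fibroblasts. Outside clusters 5, 17 and 23 of all cells the 3 medians were 1.28, 0.53 and 0.29.

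The median over all 11175 genes with at least 100 UMIs was -0.15, and the lists are to be read against that shift. Chemokines had a median of 0.26 over 21 members, of which 6 were at least 2-fold higher, with Cxcl9 and Cxcl10 highest and Cxcl5, a neutrophil attractant, at -0.53, or -1.33 in cells without marker UMIs. Cytokines and growth factors had a median of 0.26 over 24 members, with Csf3, which drives neutrophil production, at 1.95, Il6 at 1.21 and the BMP antagonist gene Grem1 at -0.71. TLR and NF-kB signalling genes had a median of 0.21 over 25 members, with Tnfaip2 at 1.09 and Nfkbiz at 0.86. Metallothionein and oxidative stress genes had a median of 0.09 over 18 members, with the antioxidant gene Gpx3 at 1.36 and the metal-binding Mt2 at 1.30. Dissociation stress genes, which respond to tissue digestion, had a median of 0.14 over 25 members, with Ier3 at 1.01 and Hsph1 at -0.86. With the same makeup of clusters the cytokine median was 0.05 and the dissociation stress median -0.05, with Csf3 at 0.44, Il6 at 0.56, Grem1 at 0.03 and Gpx3 at 0.45. That weighting leaves out cluster 5, led by Csf3, and cluster 2, which has Gpx3 among its leading genes.

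Adipocyte lineage genes moved little as groups. Adipogenic transcription factors had a median of -0.13 over 15 members and none was 2-fold higher or lower, with Klf4 at 0.50 and Ebf1 at -0.44. Preadipocyte and adventitial progenitor markers had a median of -0.09 over 17 members, with Ly6a, the surface antigen Sca-1, at 1.21 and Dpp4 at -0.54. Lipid-laden adipocyte markers had a median of 0.02 over 13 members, with the lipoprotein lipase gene Lpl at -0.56 and the fatty acid carrier gene Fabp4 at -0.99. Their percentiles among random lists were 65.2, 72.2 and 99.0. Each of these medians changed sign under an alternative setting. After trimmed mean (TMM) scaling the first was 0.04 and the second 0.15, and in cells without marker UMIs the adipocyte median was -0.08. TMM scaling moved the median of all genes from -0.15 to 0.01, so the sign changes under it went with that shift. Both list medians lay above the median of all genes with either scaling. With the same makeup of clusters Lpl was at -1.25, and in cells without marker UMIs Fabp4 was at -0.21.

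Collagen, matrix glycoprotein and hair follicle mesenchyme genes were lower in infected fibroblasts than random lists, and these differences were smaller with the same makeup of clusters. Fibrillar and basement membrane collagen had a median of -0.56 over 15 members, with 3 at least 2-fold lower, among them Col5a3 at -1.42 and Col12a1 at -1.07. Col1a1 and Col1a2, the chains of type I collagen, had log2 ratios of 0.41 and 0.54. Matrix glycoproteins and proteoglycans had a median of -0.30 over 20 members, with Aspn at -1.02 and Postn at -0.88. Hair follicle mesenchyme genes had a median of -0.89 over 6 members, with the contractile genes Acta2 at -1.31 and Tagln at -1.17, which pericytes also express. With the same makeup of clusters the medians of these 3 lists were -0.24, -0.14 and -0.17, with Col5a3 at -0.25, Col12a1 at -0.40, Acta2 at -0.18 and Tagln at -0.12. Outside clusters 5, 17 and 23 of all cells they were -0.39, -0.36 and -0.092, with Acta2 at -0.16 and Tagln at 0.025. After TMM scaling they were -0.28, -0.019 and -0.68. In cells without marker UMIs they were -0.49, -0.36 and -1.46, with Acta2 at -1.97, Tagln at -1.78 and Col12a1 at -1.56. Papillary fibroblast genes had a median of -0.30 over 10 members, with the Wnt inhibitor gene Wif1 at -1.33, and with the same makeup of clusters that median was 0.01 and Wif1 was at -0.63. The median was -0.11 after TMM scaling, -0.43 outside clusters 5, 17 and 23 of all cells and -0.44 in cells without marker UMIs, where Wif1 was at -0.36. Retinoid handling genes had a median of -0.22 over 14 members. Matrix proteases and inhibitors had a median of -0.14 over 22 members, with Mmp19 at -1.57 and Mmp9 at -1.13, and with the same makeup of clusters Mmp9 was at -0.070 and outside clusters 5, 17 and 23 of all cells at -0.20. Glycolysis and hypoxia, oxidative phosphorylation and cell cycle genes had medians of -0.08, -0.10 and -0.12, at percentiles 90.4, 52.6 and 41.0 of the random lists. After TMM scaling, which moved the median of all genes to 0.01, these were 0.17, 0.17 and 0.04, and the protease and retinoid medians were 0.09 and 0.0028.

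**Figure D3:**
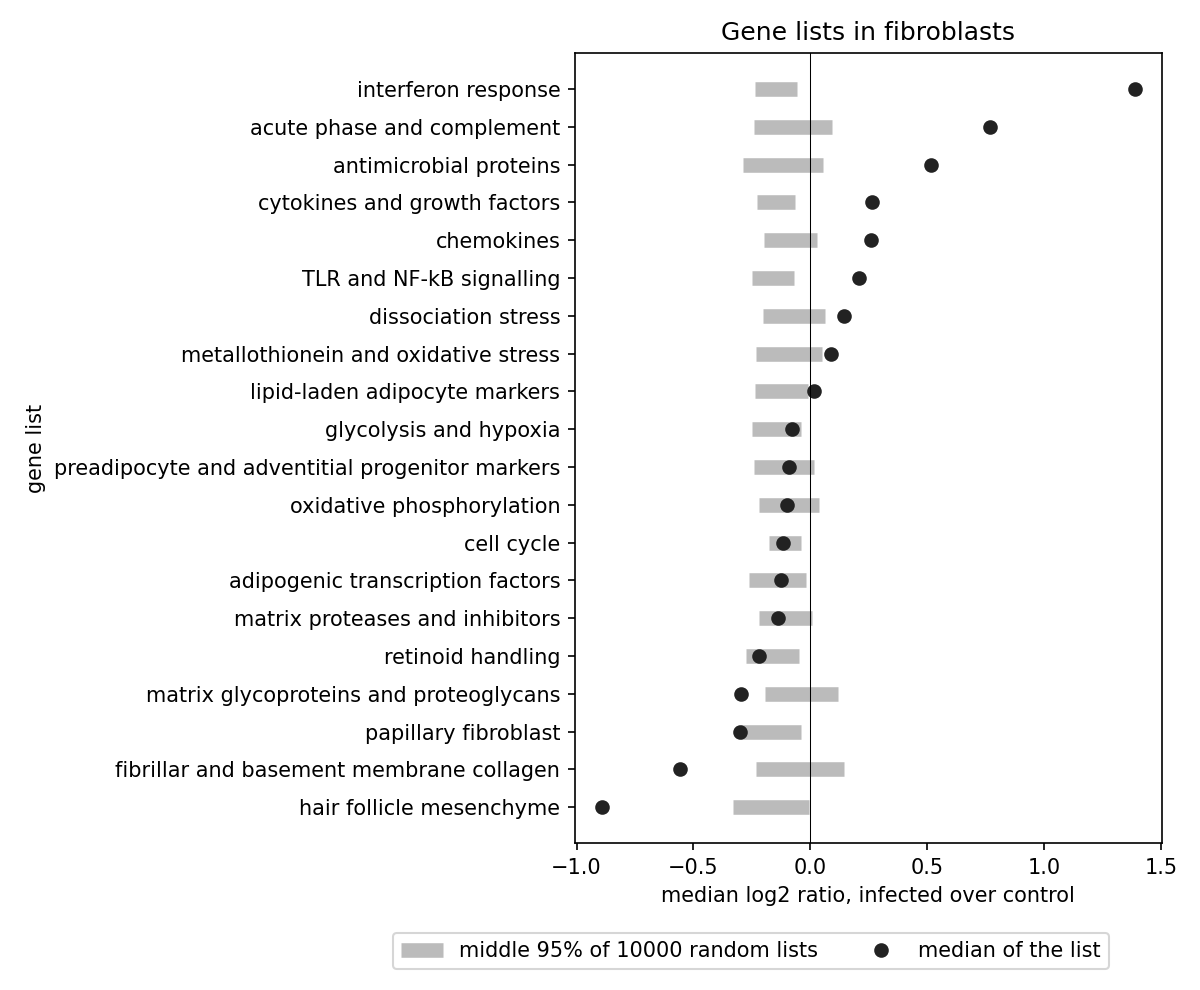
Median log2 ratio, infected over control fibroblasts, of the 20 gene lists (points), with the middle 95% of 10000 random lists matched on expression (grey bars). The interferon response list is highest at 1.39 and the hair follicle mesenchyme list lowest at -0.89.

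The authors' second clustering divided the fibroblasts into 10 clusters, and the clusters that held most of the fibroblasts differed in part between the libraries. In the control library, clusters 0, 1 and 3 held 28.5%, 28.3% and 25.9% of the fibroblasts. In the infected library, clusters 2, 0 and 1 held 21.1%, 20.8% and 16.5%. Cluster 3, led by Spp1 and Col5a3, held 7.69% of infected fibroblasts (6.98 to 8.46%), and none of its 10 leading genes differed 2-fold between control and infected cells within the cluster. Clusters 2, 5 and 6 together held 30 control fibroblasts, or 1.12% (0.760 to 1.60%), and 1838 infected fibroblasts, or 36.2% (34.8 to 37.5%). In fibroblasts without a keratin or immune marker UMI these shares were 0.360% and 11.9%. A cluster drawn almost wholly from 1 library may be that library rather than a cell type. Clusters 2, 5 and 6 are led by acute phase and response genes, including Saa2 and Saa1 in cluster 2, Csf3 and Lcn2 in cluster 5 and Ptx3 in cluster 6, so those genes are not offered as results between clusters.

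Infected fibroblasts were also assigned to the control clusters by genes that differed less than 1.5-fold between the libraries with the same makeup of clusters. Leading genes of cluster 3 passed this filter although they differed between all fibroblasts of the libraries. Among them were Spp1 (-1.50, and 0.18 with the same makeup) and Col5a3 (-1.42 and -0.25). Cluster 3 held a smaller share of infected cells here too, but this is not a check free of such genes. Its assigned share was 24.2% of control and 8.15% of infected fibroblasts. Cluster 1, led by Sfrp4 and Clec3b, took 26.6% of control and 43.6% of infected fibroblasts. Infected cells of cluster 6 were assigned to cluster 1 in 99.7% of cases and those of cluster 5 in 86.0%, while cells of cluster 2 went to cluster 0 in 54.1% and to cluster 1 in 44.0%. Of the 685 infected cells of cluster 4, 339 (49.5%) were assigned back to it and 307 (44.8%) to cluster 1, so the assigned share of cluster 1 includes cells of another cluster. The assignment matched the deposited cluster for 2322 of 2638 held-out control cells (88.0%) and 2557 of 3244 infected cells (78.8%). It was chosen after the data were seen.

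Because the study's title names antimicrobial production by preadipocytes, Camp, which encodes the cathelicidin antimicrobial peptide precursor (chromosome 9, 109847379 to 109849617, GRCm38), was measured in each population. Camp was detected in fibroblasts and myeloid cells, at 189 and 320 UMIs in control and infected fibroblasts. Its fibroblast level was 11.5 CPM (9.90 to 13.2) in control and 8.34 CPM (7.45 to 9.30) in infected cells, a log2 ratio of -0.23 against -0.15 for all genes. The counting interval of that ratio, -0.36 to -0.093, holds the median of all genes. Both Camp levels lie near the pseudocount of 10 CPM, which draws the ratio toward 0. Without a pseudocount the fold of infected over control was 0.726 (0.605 to 0.874). In myeloid cells Camp stood at 14.4 CPM (11.8 to 17.4) and 87.3 CPM (80.9 to 94.1), mostly in the neutrophil cluster 12, at 213 and 847 CPM. With every cell weighted equally the myeloid levels were 20.2 and 70.9 CPM. In keratinocytes it stood at 0.347 and 0.696 CPM.

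After each cell was thinned to 1000 UMIs, a Camp UMI was found in 0.685% of control fibroblasts (18 of 2627) and 0.587% of infected fibroblasts (29 of 4943), with 41 and 139 shallower cells left out. Without thinning the shares were 2.77% and 2.99%, at median depths of 5959 and 7494 UMIs. In myeloid cells the thinned shares were 1.51% in control (31 of 2059) and 1.64% in infected cells (34 of 2075), with 575 and 275 shallower cells left out. Without thinning the myeloid shares were 1.56% and 2.26%. The thinned share of myeloid cells with a Camp UMI thus differed little, although the myeloid level in CPM was higher in the infected library. Lymphoid cells, which should lack Camp, gave 0 of 1143 control and 0 of 2294 infected thinned cells, for which a limit of 3 counts allows shares of up to 0.262% and 0.131%, at median depths of 1277 and 1307 UMIs and with 331 and 682 shallower cells left out. The 5 fibroblasts with the most Camp UMIs held 36.0% of the control UMIs and 24.7% of the infected UMIs, and without them the log2 ratio was -0.09. Outside clusters 5, 17 and 23 of all cells it was -0.49, and in cells without marker UMIs -0.64, on 19 and 4 UMIs. Among fibroblast clusters, cluster 0, led by Cyp26b1 and Ltbp1, had 34.8 CPM of Camp (29.6 to 40.5) in control and 16.5 CPM (13.7 to 19.8) in infected cells. Infected cells of clusters 2 and 5 had 11.4 and 19.5 CPM, and fewer than 30 control cells were there for comparison.

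**Figure D4:**
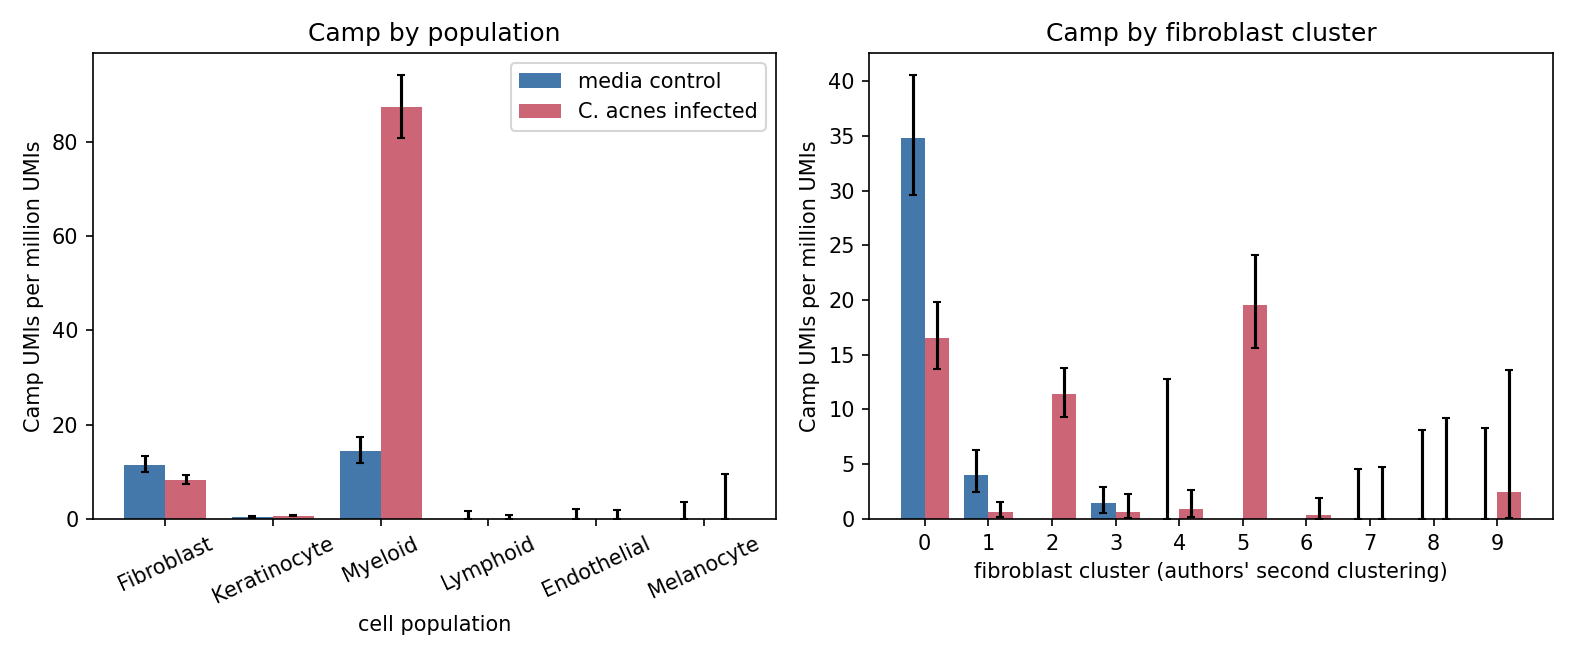
Camp level in CPM by cell population (left) and by fibroblast cluster (right) in the media control library and the C. acnes infected library; clusters 2, 5 and 6 are drawn for infected cells alone. Bars are levels and error bars are exact 95% Poisson intervals; fibroblasts stand at 11.5 and 8.34 and myeloid cells at 14.4 and 87.3.

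The same comparison was made in the other 4 large populations, and interferon-inducible genes were higher in the infected library in each. The interferon response list had a median log2 ratio of 0.95 in keratinocytes, 2.23 in myeloid cells, 0.91 in lymphoid cells and 1.21 in endothelial cells. At least 2-fold higher were 10 of 24 members in keratinocytes, 18 of 23 in myeloid cells, 9 of 19 in lymphoid cells and 13 of 24 in endothelial cells. Ifng, the gene of interferon gamma, stood at 29.6 CPM in control and 2012 CPM in infected lymphoid cells, with 67 and 10048 UMIs. Cxcl9 was among the 5 highest genes in keratinocytes, at 11.3 and 458 CPM, in endothelial cells, at 56.0 and 517 CPM, and in myeloid cells, with 4 and 3481 UMIs. The lymphoid population leaves out cluster 20, and the lymphoid cluster 10, in which Ifng is a leading gene, held 134 control and 937 infected cells.

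Other high genes in keratinocytes were Gbp2, Cxcl10 and Iigp1, at log2 ratios of 3.74, 3.44 and 3.04. In myeloid cells they were Cxcl10 at 5.43, Gbp2 at 5.09, the immunoglobulin gene Igkc at 4.43 and Ifi47 at 3.82. In lymphoid cells the chemokine gene Ccl4 had a log2 ratio of 3.20. In endothelial cells Gbp2 stood at 3.09, and the ubiquitin-like gene Ubd had 5 and 344 UMIs. Among the low genes, keratinocytes had less of the neuropeptide gene Npy (-1.97), the lipid desaturase gene Scd1 (-1.67), Gzmc (-1.60) and the lipid carrier gene Apoe (-1.55). Myeloid cells had 286 and 1 UMIs of Retnla, a marker of alternatively activated macrophages, and lower Mmp19 (-1.95), Ccl17 (-1.52) and Mcpt4 (-1.41). Lymphoid cells had lower Mest (-1.73), Apoe (-1.52), Havcr2 (-1.37) and Palld (-1.29), and endothelial cells had lower Sncg (-1.97), Fabp4 (-1.84), C1qtnf9 (-1.67) and Acta2 (-1.59). Apoe stood at 403 and 134 CPM in control and infected lymphoid cells, against 8874 and 3020 CPM in keratinocytes. The pericyte gene Rgs5 was also lower in endothelial cells, at 181 and 86.5 CPM. RNA from other cell types was not tested as a source of these values. Xist was the lowest gene in each of the 4 populations, and the Y-linked genes Ddx3y, Uty and Eif2s3y were among the highest in some of them. Cluster makeup also differed within these populations. Keratinocyte cluster 2, with Npy among its leading genes, held 36.9% of control and 23.3% of infected keratinocytes. Myeloid cluster 3 held 64.6% of control and 33.1% of infected myeloid cells. Weighting to the same makeup of clusters was not run here, so makeup and changes within cells were not separated.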

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

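The tests of free RNA, of neutrophil RNA and of sex or other differences between the animals were chosen after the results they measure were seen. The removal of the 5 Camp-richest cells was also chosen after the data were seen, but its bounds were set before its own result was. Gzmc, a granzyme gene, differed in opposite directions between populations, and the difference was not tested: its log2 ratio was 1.07 in myeloid cells (194 and 514 UMIs), -1.60 in keratinocytes (1807 and 221 UMIs) and 3.52 in endothelial cells (1 and 216 UMIs, a ratio of 187 with a counting interval of 33.1 to 7404). Y-linked genes gave, in libraries whose labels state no sex, 2 UMIs in the control library and 23169 in the infected library. The 1061 infected cells classed Fibroblast but left out of the second clustering had Il1b at 594 CPM, against 373 CPM in the 531 control cells left out and 10.0 CPM in the infected cells kept.

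Interferon-response genes were higher in infected fibroblasts, with a list median of 1.39. Free RNA from other cells as the whole cause is argued against for the 16 members at least 2-fold higher. Their levels were a median of 7.41 times the lowest other population's, with 13 of them over 3 times. For most of them that population was the keratinocytes, whose infected cells were deeper (median of 15919 UMIs, against 7494 in fibroblasts). An equal amount of free RNA per cell would therefore give a lower CPM there. Doublets as the whole cause are argued against by a list median of 1.55 in the 278 control and 252 infected fibroblasts without a keratin or immune marker UMI, which were shallower in the infected library (medians of 4113.5 and 1460.5 UMIs). Sex or another difference between the animals cannot be told apart from infection, since the infected library alone carried 23169 Y-linked UMIs and each group is 1 library.

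Camp was slightly lower in infected fibroblasts, at a log2 ratio of -0.23 against -0.15 for all genes. The pseudocount of 10 CPM draws this ratio toward 0, and with 1 CPM it was -0.42 against -0.25 for all genes. Subset makeup is argued against by a ratio of -0.51 with the same makeup of the 7 clusters shared by both libraries, which leaves out the infected clusters 2 and 5, where Camp stood at 11.4 and 19.5 CPM. Free neutrophil RNA is argued against as the source of fibroblast Camp, since control fibroblasts had 47.2 Camp UMIs per Ngp UMI, on 189 and 4 UMIs, against 0.135 in the neutrophil cluster. A few rich cells stay open as the cause of the overall difference, because without the 5 richest cells per library the ratio was -0.093, between the bounds set for that test.

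Fibroblast clusters 2, 5 and 6 held 1.12% of control and 36.2% of infected fibroblasts. A first comparison of depths gave a median UMI ratio of 1.33 between infected cells inside and outside these clusters and did not decide, so a depth-matched test replaced it after that ratio was seen and before its own result was. Among fibroblasts of 4436.5 to 7535 UMIs the clusters held 26.1% of infected (24.0 to 28.3%) and 1.12% of control cells (0.630 to 1.85%), which argues against depth as the whole cause, although the share was 11.9% in the shallower infected cells without marker UMIs. Sex or another difference between the animals cannot be told apart from infection here, as the control library had 2 Y-linked UMIs and the infected library carried the rest.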

How the results depend on the processing

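The whole Fibroblast class, the fibroblasts outside clusters 5, 17 and 23 of all cells, the removal of the 5 Camp-richest cells and the antimicrobial list without S100a8 and S100a9 were settings chosen after the data were seen. No paired analysis was possible because there was 1 library per group. The interferon response median stayed above 1 in fibroblasts under each setting run on it. The median of all genes in fibroblasts was -0.15, 0.01 with TMM, -0.25 and -0.06 with pseudocounts of 1 and 50 CPM and -0.07 with the same makeup. Values below that left the counting interval of the reported value are given by setting, and the cause was not tested, except that pseudocounts shrink or widen ratios, thinning lowers shares, the same makeup leaves out clusters 2, 5 and 6 and the removal of cells with marker UMIs sets S100a8 and S100a9 to 0 by construction. TMM gave 3.42 and -1.31 for the medians of the 12 highest and 12 lowest fibroblast genes, -0.088 for Camp, and for lists 0.79 (antimicrobial), 0.044 (adipogenic, changing sign together with the median of all genes), 0.54 (chemokines), 1.66 (interferon) and 1.05 (acute phase). For the 5 highest and lowest genes TMM gave 3.54 and -1.56 in keratinocytes, -1.80 for the lowest in myeloid cells and 4.85 and -1.37 in lymphoid cells. A pseudocount of 1 CPM gave 4.25 and -1.81 for the fibroblast medians, -0.42 for Camp, -0.23 (adipogenic), 0.37 (chemokines) and 1.44 (interferon), with 4.96 and -2.29 in keratinocytes, 5.57 and -2.82 in myeloid cells, 6.69 for the highest in lymphoid and 5.48 in endothelial cells. A pseudocount of 50 CPM gave 2.15 and -1.12, -0.076 for Camp, 0.45 (antimicrobial), 1.05 (interferon) and 0.74 (acute phase), with 2.15 and -1.25 in keratinocytes, 3.29 and -0.83 in myeloid, 2.65 and -1.18 in lymphoid and 2.10 and -1.10 in endothelial cells. The same makeup of clusters gave -0.65 for the 12 lowest, -0.51 for Camp, 0.049 (antimicrobial), -0.19 (adipogenic), 0.19 (chemokines), 1.28 (interferon) and 0.17 (acute phase), and among the results that changed sign were the adipocyte list (-0.0051), dissociation stress (-0.046), the papillary list (0.012) and Spp1 (0.18). Fibroblasts without a keratin or immune marker UMI gave 3.46 for the 12 highest, -0.64 for Camp, 0.00 (antimicrobial, with S100a8 and S100a9 at 0 by construction), 0.015 (adipogenic, changing sign), 0.44 (chemokines), 1.55 (interferon) and -0.082 (adipocyte, reversed), and clusters 2, 5 and 6 held 0.360% of control and 11.9% of infected cells. Without S100a8 and S100a9 the antimicrobial median was 0.22 in all fibroblasts and 0.0037 in those without marker UMIs. Equal weight per cell gave 3.26 for the 12 highest, 0.39 (antimicrobial) and 0.73 (acute phase), and Camp at 20.2 and 70.9 CPM in control and infected myeloid cells. The whole Fibroblast class gave 3.26 for the 12 highest, -0.50 for Camp, 0.33 (antimicrobial), 0.59 (chemokines) and 0.79 (acute phase). Fibroblasts outside clusters 5, 17 and 23 of all cells gave 3.04 and -1.26 for the 12 highest and lowest, -0.49 for Camp, 0.29 (antimicrobial), -0.20 (adipogenic), 0.35 (chemokines), 1.28 (interferon), 0.53 (acute phase), -0.033 (adipocyte, reversed) and 0.025 for Tagln (reversed). Without the 5 Camp-richest cells Camp was -0.093. Without the 5% deepest and 5% shallowest cells the log2 share ratio was -0.53 for keratinocytes and -0.46 for myeloid cells, and the 12 lowest gave -1.63. Camp UMIs were found in 2.77% of control and 2.99% of infected fibroblasts without thinning, and in 0.335% of infected fibroblasts thinned to 500 UMIs. For the 15 other lists, 39 of 120 values stayed within the counting interval and 17 changed sign. Those 17 included the progenitor, protease, retinoid, glycolysis, cell cycle and oxidative phosphorylation lists under TMM, where the median of all genes also changed sign. The sign changes under TMM went with that shift, and the remaining ones arose under other settings. For 96 single genes, 325 of 864 values stayed within the counting interval and 28 changed sign, among them Ntn1, Sod1 and Sod3 under TMM. Depth limits Camp, with 189 and 320 UMIs in fibroblasts.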

Other observations

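The grouping of interferon genes used here was chosen after the data were seen, and its test in the other populations was set before that result was seen. In fibroblasts the guanylate-binding protein and immunity-related GTPase genes had a median log2 ratio of 2.80 over 9 genes, and the Ifit and Mx genes 0.42 over 4. Ifit1 was nevertheless at least 2-fold higher, and Mx1 stood at 2.00 and 2.53 CPM, where the pseudocount of 10 CPM shrinks a ratio. The first group lay above the second in 5 of the 5 other populations, by 1.71 in keratinocytes, 2.52 in myeloid cells, 1.23 in lymphoid cells, 1.90 in endothelial cells and 1.30 in melanocytes. In infected keratinocytes Ifit1 itself stood at 7.21 CPM, under the pseudocount, which holds such ratios near 0. The gap between the groups may therefore be partly set by low Ifit and Mx levels, and the 5 of 5 does not decide between these readings. Ifng stood at 29.6 and 2012 CPM in control and infected lymphoid cells. A candidate explanation, as a hypothesis from these 2 libraries alone, is that interferon gamma reached each of these populations, and sex or another difference between the animals stays open.

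Acute phase and complement genes were also higher outside the fibroblasts, with list medians of 1.12 in keratinocytes (10 of 17 members at least 2-fold higher), 0.71 in myeloid cells (3 of 13), 1.01 in lymphoid cells (5 of 9) and 0.72 in endothelial cells (4 of 13). Fibroblast transcripts were also higher in keratinocytes, where Col1a1 stood at 165 and 444 CPM and the collagen and matrix glycoprotein lists had medians of 0.17 and 0.36, and in lymphoid cells, where Col1a1 stood at 66.8 and 113 CPM. In myeloid and endothelial cells the collagen lists were lower instead, with medians of -0.30 and -0.41. Col1a1 stood at 167 and 204 CPM in control and infected myeloid cells and at 435 and 560 CPM in endothelial cells. RNA from fibroblasts was not tested as a source of these acute phase values. Chemokine lists had medians of 0.60, 0.35 and 0.87 in keratinocytes, myeloid cells and endothelial cells and 1.56 in lymphoid cells, where 8 of 13 members were at least 2-fold higher.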
